A study of Caenorhabditis elegans with 2 samples.

How the data were processed

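Whole L4 worms of 1 transgenic strain were assayed by ChIP-seq against MDL-1, per the labels, in 2 biological replicates with fragmentation by sonication. The deposited files are peak lists on genome builds ce10 and ce11. For each build they comprise a relaxed candidate list for replicate 1, for replicate 2 and for the pooled replicates, and an optimal list kept after the authors tested reproducibility by the irreproducible discovery rate (IDR). Per the text files deposited with the libraries, each replicate's candidate list came from its own alignment and 1 further parent, and the optimal list came from both replicate lists and the pooled list. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here, and control libraries were not used here. Peaks were thus called per replicate and on pooled data.

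The signal of each region is the value the authors' peak caller gave it, on a scale of its own in each deposited list, so it served only to rank and describe peaks within a list. The deposited −log10 q-value had the same maximum (3.34) in 1095 of the 1115 optimal peaks and was therefore not used for ranking. The optimal list was exactly the 1115 regions of highest signal in the pooled list, with 48.2 as its lowest signal. Most pooled regions had a width of 396 bp, and those of replicate 1 had 390 bp and of replicate 2 410 bp. Summits were taken from the deposited offsets. In 2 optimal peaks the offset reached past the interval and was used as given, and 2 optimal peaks shared 1 interval with different summits. The depth per library is unknown, and no value was compared in size between replicates except by rank or correlation. As the only group had 2 replicates, no test between samples was made. P-values refer to peaks or genes within these lists, and neighbouring peaks are not independent.

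Coordinates are on ce11, the build of the reference sequence and of the Ensembl release 115 annotation (WBcel235), and each ce11 region fitted within the reference chromosomes. The ce10 lists were used only for counts and overlaps. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and overlaps were checked with bedtools 2.31.1. Regions were ranked by signal. The replicates were compared over as many top regions as there were optimal peaks, with 1 bp as the minimum overlap and 1000 circular shifts for chance. A gene was called bound when an optimal summit lay from 1000 bp upstream to 200 bp downstream of any annotated 5' end of its protein-coding transcripts, so that 1 summit can count for several genes. The background was all 19973 nuclear protein-coding genes, and the whole nuclear genome was used in place of its mappable part, which was not determined.

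The 31 gene lists and 14 motifs were fixed before the data were examined. Lists were tested with Fisher's exact test, two-sided, and motifs and hexamers (merged with their reverse complements) with the exact McNemar test between windows of 50 bp either side of the summit and the same windows 500 bp downstream. Benjamini-Hochberg adjustment was made over the lists, the preset motifs, the 2080 hexamers, 6 chromosomes, 5 features or 5 RNA classes, with 0.05 as the threshold. Each of the weaker candidates below the threshold (28885 regions) came from the pooled list. Named genes were, by a rule set in advance, those with an optimal summit in the promoter window among the 25 strongest peaks, up to 4 bound members of each list with the highest peak signal, and mdl-1, mxl-1, klu-1 and unc-119. Analyses of annotated features at summits, distances to 5' ends, bases flanking the E-box, peak classes and regions ranked below the threshold, and gene lists for peaks with or without CACGTG, were chosen after the data were seen. The gene nhr-49 and the genes nearest to 4 distal peaks were named outside this rule.

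The code was tested on simulated data. With CACGTG planted in 200 of 1115 random windows it came first of 2080 hexamers, and without planting no hexamer passed. These windows lacked the difference in base content between real summits and flanks, so calls due to base content were not measured. With 635 random genes as bound, 4 of 100 draws called any list, and 12 planted ribosomal protein genes were recovered in 100 of 100. These draws gave each gene an equal chance, whatever its number of annotated 5' ends. Random positions fell in promoter windows in 26.2% of cases. A reproducibility model fitted to 10000 simulated pairs returned a reproducible share of 0.302 for a true 0.3, and 5.3% of the pairs it passed at 0.05 were false.

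Alternatives covered a stricter peak set, a reproducibility model fitted to the replicate lists at 0.05 and 0.01, the ce10 lists, the overlap rule, the number of regions compared, the promoter window, the assignment to genes, the gene background, the motif window and its comparison, the expectation for chromosome X, the distance to RNA genes, and leaving out each replicate. In the last, the 1115 strongest regions of the remaining replicate took the place of the optimal peaks.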

Results

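Chromatin immunoprecipitation followed by sequencing (ChIP-seq) mapped where MDL-1 sits on the genome of Caenorhabditis elegans at the fourth larval stage (L4). MDL-1 is a Mad-like transcription factor of the basic helix-loop-helix leucine zipper class, and MXL-1 is its Max-like partner. The worms were whole animals of a transgenic strain of pooled sex that carries an insertion for mdl-1 in an unc-119 mutant background. A note in the labels gives a C-terminal GFP-FLAG tag but names KLU-1 as the tagged protein, whereas the other labels name MDL-1. The series held 1 group with 2 biological replicates and no second condition. The comparisons were therefore between the replicates, between the authors' reproducible ("optimal") peaks and the weaker candidate regions, and between peak summits and their flanks. The optimal list on genome build ce11 held 1115 peaks, and each candidate list, for replicate 1, replicate 2 and the pooled data, held 30000 regions. Read depth is unknown because the peak lists carry no read totals, so the shares below carry exact (Clopper-Pearson) 95% intervals that cover the counting of peaks only.

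The strongest peak of all lay upstream of mdl-1 itself. That peak (X: 6737497-6738030, intergenic) had a signal of 701 and its summit was 4571 bp upstream of the 5' end of mdl-1 and 4479 bp upstream of R03E9.2, the nearest 5' end, a gene named after its values were seen. It ranked 1 in the pooled list, in replicate 1 and in replicate 2, and it held 1 CACGTG sequence within 50 bp of the summit. The next peak (X: 14818751-14819181, signal 523) lay 438 bp upstream of epn-1, which encodes an epsin of the endocytic pathway. A peak of signal 381 (X: 15607525-15607827) lay 300 bp upstream of nipi-3, a Tribbles-like pseudokinase of the innate immune response. The promoter windows of dpsm-1 (signal 309.6), tos-1 (305), the gene pair ipla-6 and mif-4 (268, 1 shared peak), nspc-17 (266), srh-2 (266) and ZK470.2 (252) held the other named peaks among the 25 strongest. The summit at srh-2 was in an annotated 5' UTR and that at ZK470.2 in an intron, while the others were intergenic.

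Of the 25 strongest peaks, 8 had a summit in a promoter window of a protein-coding gene and 17 did not. Examples of the latter, chosen after their values were seen, had their nearest 5' ends at egl-9 (signal 491, summit 1785 bp upstream), ogt-1 (326, 2043 bp upstream) and atgl-1 (290.4, 1807 bp upstream). The gene egl-9 encodes the prolyl hydroxylase that controls HIF-1, ogt-1 the O-GlcNAc transferase and atgl-1 a triglyceride lipase. The summit near atgl-1 was in a 3' UTR. Each of the 25 peaks ranked 38 or better in replicate 1 and 74 or better in replicate 2, and 12 of them held a CACGTG.

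The replicates shared most of their strongest regions. Of the 1115 highest-ranked regions of replicate 1, 718 (64.4%, interval 61.5% to 67.2%) overlapped a region of the same rank range in replicate 2 by at least 1 bp. Circular shifts of the regions within chromosomes gave a mean of 0.9%, and no shift reached the observed share (permutation p = 0.001, the smallest that 1000 shifts can give). Of the optimal peaks, 1113 were in the candidate lists of both replicates and 717 (64.3%) were among the 1115 strongest regions of both. A further 22.2% were among the strongest regions of replicate 1 only and 10% of replicate 2 only. As the optimal list was drawn from these same libraries, its shares are no independent measure of reproducibility. The peaks at rps-1 (rank 70 in replicate 1 and 85 in replicate 2), hlh-11 (124 and 37) and epn-1 (3 and 2) ranked high in both, whereas those at the genes pro-1 (521 and 13046) and peb-1 (430 and 12764), chosen after their values were seen, ranked far lower in replicate 2. The signals of the replicates were compared across 1113 peaks, which were selected on pooled signal and are not independent replicates. Spearman's rho was 0.588 and Pearson's r was 0.661 on the log2 scale.

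The signal around mdl-1 stood out among all genes, and that around klu-1 and unc-119 did not. The gene klu-1 was examined because 1 note in the labels of both libraries names KLU-1, a zinc finger protein, as the tagged protein. The other labels name MDL-1. Signal around mdl-1 and unc-119 was examined as well, because a multicopy insertion can raise signal around the inserted gene. Within 20 kb of mdl-1 (X: 6742351-6743899) the summed signal of the pooled candidate regions was 1796, above that of 99.97% of the 19973 protein-coding genes, whose median was 213. The percentile was 99.98 in replicate 2 and 99.99 in replicate 1. In that range lay 7 optimal peaks, all upstream of mdl-1. Those with summits at X: 6728429, 6729220 and 6729758 lay beyond R03E9.2 (X: 6729998-6733301) as seen from mdl-1, in or beside another gene. Windows around neighbouring genes share these regions, so the signal cannot be assigned to mdl-1 alone. The percentiles of klu-1 (I: 14975419-14980596) were 59.1 in the pooled list, 58.6 in replicate 1 and 76.9 in replicate 2. Those of unc-119 (III: 10902641-10908935) were 72.9, 67.5 and 47.8. No optimal peak lay within 20 kb of klu-1 or unc-119. The gene mxl-1 (V: 11244839-11245926) had 1 optimal peak in that range, of signal 53.8, with its summit 15884 bp upstream, and its pooled percentile was 55.3.

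**Figure D1:**
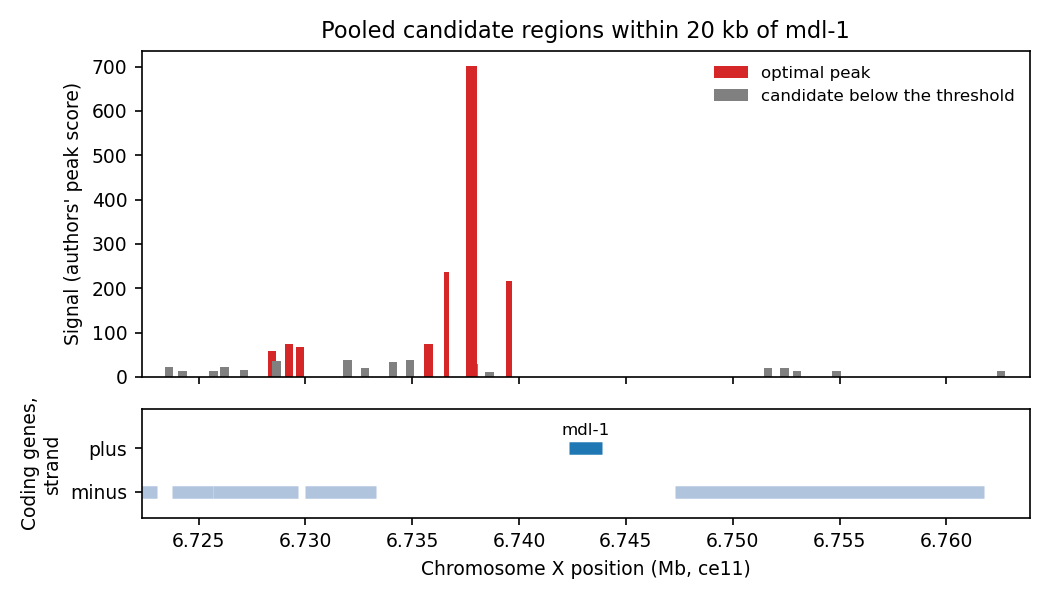
Pooled candidate regions around mdl-1 on chromosome X (position in Mb on ce11, horizontal), each drawn to its width with the authors' signal as its height, above the protein-coding genes on each strand, with optimal peaks in red and weaker candidates in grey. The highest bar, of signal 701, has its summit 4571 bp upstream of mdl-1, and the optimal peaks all lie on its upstream side.

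Optimal peaks were mostly intergenic, and as a set they were nearer to gene starts than the weaker candidates as a whole. Summits were intergenic in 725 of 1115 peaks (65.0%, interval 62.1% to 67.8%), in introns in 311 (27.9%), in 5' UTRs in 44 (3.95%), in 3' UTRs in 18 (1.61%) and in coding exons in 17 (1.52%). Among the 28885 candidate regions below the threshold, 43.5% of summits were intergenic and 12.3% were in coding exons. Fisher's exact test, adjusted over 5 features, gave p = 5.9e-45 for intergenic sequence, 9.6e-40 for coding exons and 5.6e-05 for 5' UTRs. Promoter windows, from 1000 bp upstream to 200 bp downstream of an annotated protein-coding 5' end, held 554 summits (49.7%, interval 46.7% to 52.7%). The windows covered 26.2% of the nuclear genome (exact binomial p = 2.2e-62), and they held 32.1% of the weaker summits (Fisher's exact test, two-sided, p = 7.4e-33). By rank, the windows held 41% of ranks 1 to 100, 50.9% of the weaker candidates at ranks 1116 to 1500 and 27.9% of those at ranks 20001 to 30000. The median distance from a summit to the nearest 5' end was 858 bp for optimal peaks and 1185 bp for the weaker candidates.

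These peaks assigned 635 protein-coding genes (3.18% of all), and genes for stress and longevity regulators were over-represented among them. Of the 24 listed transcription factors of longevity and stress, 8 were bound (33.3%, 10.5 times the share of all genes, adjusted p = 1.5e-05 by Fisher's exact test over 31 lists). The ratio was 5.04 against genes with any candidate region in the window (adjusted p = 0.0025) and 3.42 with peaks counted once among candidate regions (adjusted p = 0.023, Fisher's exact test in both). Genes with several annotated 5' ends have more windows, and the test over all genes did not adjust for this. The windows of these 24 genes held 63 pooled candidate regions, and those of the 82 cytosolic ribosomal protein genes held 81. The bound genes were zip-2, hlh-30, atf-4, xbp-1, nhr-49, daf-16, lin-14 and hif-1. The bZIP gene zip-2, of the response to infection, had a peak of signal 137 at III: 833687-834082, in an intron and 203 bp upstream of its nearest 5' end. The TFEB-like gene hlh-30 had a peak of rank 188 at IV: 4028243-4028638, in an intron and 314 bp upstream of an alternative 5' end. The peak at atf-4 had a signal of 120.3 and lay 170 bp upstream, and that at xbp-1, a regulator of the unfolded protein response, had a signal of 100.8 in the 5' UTR. Of these, nhr-49 was named after its values were seen.

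Cytosolic ribosomal protein genes formed the other over-represented list. Of 82 members, 12 were bound (14.6%, 4.60 times the share of all genes, adjusted p = 0.00016 by Fisher's exact test). The strongest peaks were at rps-1 (signal 185, 266 bp upstream), rps-12 (157, 162 bp upstream), rpl-15 (135, 346 bp upstream) and rpl-3 (121, 284 bp upstream), all intergenic. The call was lost against genes with any candidate region in the window (ratio 2.29, adjusted p = 0.054) and with the 557 strongest peaks (ratio 3.87, adjusted p = 0.074 by Fisher's exact test). Mitochondrial ribosomal proteins had 1 of 70 members bound (mrps-7), with an adjusted p of 0.809.

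The other 29 lists did not pass the threshold, and several growth and turnover pathways had values just beyond it. Insulin and TOR signalling had 4 of 23 members bound (ratio 5.47, adjusted p = 0.057 by Fisher's exact test, as for each list here), namely ftt-2 (signal 120.5), akt-2 (85.2), par-5 (76.3) and the FOXO gene daf-16 (71.9). Autophagy had 4 of 27 (ratio 4.66, exact test, adjusted p = 0.062), namely atg-9 (95.7), lgg-1 (95), lgg-2 (93.0) and atg-18 (54.1). The vacuolar ATPase and lysosome list had 4 of 31 (ratio 4.06, exact test, adjusted p = 0.083), with imp-2 (94.6) and the proton pump subunits vha-12 (80.1), vha-13 (56.6) and vha-1 (49.5). Its ratio was 2.13 without replicate 1 (exact test, adjusted p = 0.441) and 3.11 without replicate 2 (0.244). Nuclear hormone receptors had 16 of 274 (5.84%, ratio 1.84, exact test, adjusted p = 0.096), led by nhr-1 (154), nhr-32 (134), nhr-135 (121) and nhr-58 (102). Cuticle collagens had 0 of 174 (Fisher's exact test, adjusted p = 0.057, unadjusted p = 0.0074). The translation factors eef-1A.2 (241), iff-2 (190.2), eif-2Bgamma (67.8) and eef-1A.1 (57.2) made 4 of 39 (ratio 3.23, exact test, adjusted p = 0.134). With peaks assigned to the single nearest 5' end, the adjusted p by the exact test was 6.6e-05 for insulin and TOR signalling, 0.0064 for autophagy and 0.00021 for nuclear hormone receptors. The vacuolar ATPase list (adjusted p = 0.356), translation factors (0.493) and collagens (5 of 174, 0.645) did not pass in that exact test. Against genes with a candidate region in the window, the exact test gave adjusted p = 0.257 for insulin and TOR signalling, 0.356 for autophagy and 0.577 for nuclear hormone receptors. Collagens passed as lower there (0 of 80, exact test, adjusted p = 0.041) and with 2000 bp upstream to 500 bp downstream (1 of 174, 0.032).

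Heat shock and chaperones had 5 of 60 members bound (exact test, adjusted p = 0.144), among them dnj-13 and hsp-1 (70.7). Basic helix-loop-helix factors had 3 of 41 (exact test, adjusted p = 0.397), namely hlh-11 (177), hlh-30 and hif-1 (55.4). The Myc-Mondo-Mad network had 1 of 6 (hlh-30, exact test, adjusted p = 0.420). Lipid metabolism had 3 of 44 (acs-2, pmt-1 and cept-2, exact test, adjusted p = 0.420), glycolysis 2 of 19 (hxk-3 and ldh-1, adjusted p = 0.375) and histones 4 of 81 (adjusted p = 0.588). With peaks assigned to the single nearest 5' end, the exact test called the Myc-Mondo-Mad network (4 of 6, adjusted p = 0.00043), basic helix-loop-helix factors (7 of 41, 0.0094), heterochronic and molting genes (5 of 19, 0.0064), lipid metabolism (0.012) and glycolysis (0.031). The other 7 alternatives set before the data were seen gave the Myc-Mondo-Mad network 1 or 2 bound members and an adjusted p of 0.076 to 0.682 by the exact test. Between 0 and 2 members were bound in the lists for cathepsins (1 of 28), nucleotide synthesis (1 of 20), tRNA synthetases (0 of 31), ribosome biogenesis (1 of 28), the proteasome (2 of 33), the respiratory chain (2 of 46), homeobox factors (1 of 92), EGR and Kruppel zinc fingers (0 of 16), the cell cycle (2 of 38), germline (1 of 72) and heterochronic and molting genes (1 of 19, lin-14). The tissue marker lists had 0 of 24 members for intestine, 2 of 30 for body wall muscle, 1 of 18 for pharynx, 2 of 38 for neurons and 0 of 25 for hypodermis. None of these lists had an adjusted p below 0.547.

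The sequence CACGTG, the E-box that Max-partner proteins are known to bind, marked the summits. It lay within 50 bp of 214 of 1115 summits (19.2%, interval 16.9% to 21.6%) and in 22 of the windows 500 bp downstream (1.97%, interval 1.24% to 2.97%), a ratio of 9.73 (exact McNemar test, adjusted p = 2.2e-42 over 14 preset motifs). Peaks with a CACGTG included those at tos-1, ipla-6, nhr-32, hlh-11, hxk-3 and atg-9. The variant CACGCG was in 10.3% of summit windows and 0.897% of flanks (exact McNemar test, adjusted p = 3.2e-23). The E-boxes of other helix-loop-helix classes did not pass the threshold, with CAGCTG in 3.32% against 2.24% (exact McNemar test, adjusted p = 0.173) and CATATG in 1.26% against 2.51% (adjusted p = 0.058).

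The repeat GAGAGA was more frequent still, in 407 summit windows (36.5%, interval 33.7% to 39.4%) against 5.47% of flanks (ratio 6.67, exact McNemar test, adjusted p = 1.4e-70). The EGR-type site GCGTGG was in 5.11% of summits against 1.43% of flanks (exact McNemar test, adjusted p = 2.1e-06), and GTGGGC was in 3.23% against 1.79% (adjusted p = 0.058). The GC box GGGCGG was in 7.17% against 2.24% (exact McNemar test, adjusted p = 9.9e-08). TATAAA (5.74% against 12%, exact McNemar test, adjusted p = 4.5e-07) and TTTTTT (19.4% against 40.9%, adjusted p = 2.9e-27) were lower at summits. The E-box with flanking T and A, TCACGTGA, was in 9 summit windows and 0 flanks (exact McNemar test, adjusted p = 0.0068). That call was lost with windows of 25 bp either side (adjusted p = 0.318), with the upstream flank (0.102) and with the 557 strongest peaks (0.097, exact tests). The GATA site TGATAA (adjusted p = 0.058), the DAF-16 element GTAAACA (adjusted p = 0.931) and ATCATC (adjusted p = 1) did not pass in the exact McNemar test. TGATAA passed as lower at summits by the exact test with windows of 25 bp (adjusted p = 0.044) and 100 bp (0.017), the upstream flank (0.034) and the 557 strongest peaks (0.046). GTGGGC passed as higher with 100 bp (0.0026), and CAGCTG without replicate 2 (3.41% against 1.79%, adjusted p = 0.038), all by the exact test.

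Summit windows were 48.4% G and C and the flanks 35.6%, so the motifs were also set against 1115 weaker summits of matched base content. The ratio of CACGTG fell from 9.73 to 4.12 (19.2% against 4.66%, Fisher's exact test, adjusted p = 1.5e-26), that of GAGAGA from 6.67 to 2.33 (adjusted p = 3.0e-28), and that of CACGCG from 11.5 to 2.21 (10.3% against 4.66%, adjusted p = 2.2e-06). GCGTGG (ratio 0.851), GGGCGG (0.930) and TTTTTT (0.919) no longer differed, and TATAAA turned to a ratio of 1.39 (Fisher's exact test, adjusted p = 0.224).

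**Figure D2:**
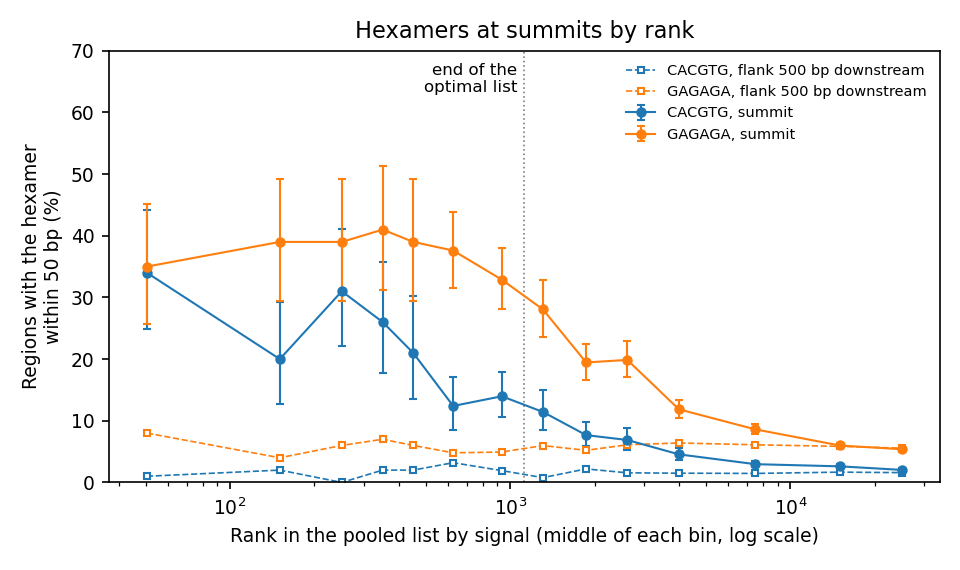
Share of regions (%) with CACGTG (blue) or GAGAGA (orange) within 50 bp of the summit, by rank in the pooled list (log scale), with exact 95% intervals, the share in the windows 500 bp downstream (dashed), and the end of the optimal list at rank 1115 (dotted line). Among ranks 1 to 100, 34% of regions hold CACGTG and 35% GAGAGA, and both shares fall toward the flanks among ranks 20001 to 30000 (2.03% and 5.38%).

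In the scan of all 2080 hexamers, 528 were higher and 416 lower at summits than in flanks. Among those higher at summits GAGAGA had the smallest p, and AGAGAC (25.7% against 3.86% of windows), CGTCTC (24.8% against 3.68%), CACGTG, ACGCAG (20.1% against 2.33%) and AGACGC (19.4% against 2.33%) were among the 7 smallest. The smallest p of all hexamers was that of AAAATT, which was lower at summits (9.33% against 46.2%). Higher hexamers made up 55.9% of those that passed. Against summits of matched base content 104 hexamers were higher and 135 lower, so that 43.5% were higher. AGAGAG, GAGAGA and CACGTG were the 3 highest-ranked of these, and AGACGC was in 19.4% against 8.34% (Fisher's exact test, adjusted p = 7.3e-12).

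**Figure D3:**
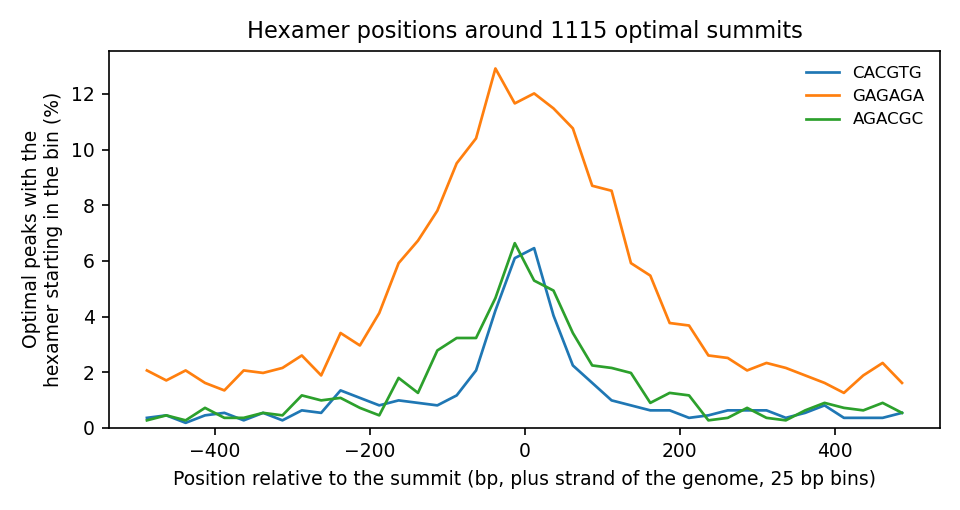
Share of the 1115 optimal peaks (%) with CACGTG, GAGAGA or AGACGC on either strand starting in each 25 bp bin, by distance from the summit in bp. CACGTG peaks at 6.46% in the bin just right of the summit and is at 2.24% in the bin starting 50 bp from it, while GAGAGA is spread more widely and reaches 12.9%.

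Chromosome X carried the most peaks for its length. It held 289 peaks (25.9%, interval 23.4% to 28.6%), 16.3 per Mb, and makes up 17.7% of the nuclear genome (exact binomial test, adjusted p = 4.0e-11 over 6 chromosomes). Chromosome III was also above its length (17.4% of peaks, 13.7% of length, exact binomial test, adjusted p = 0.0012). Chromosomes V (15.5% against 20.9%, exact binomial test, adjusted p = 2.0e-05), IV (13.7% against 17.4%, adjusted p = 0.0014) and I (12.4% against 15%, adjusted p = 0.016) were below, and II did not differ (adjusted p = 0.901). Among the weaker candidates 21.0% were on X, less than among optimal peaks (ratio 1.23, Fisher's exact test, p = 0.00012). By rank the share on X was 41% at ranks 1 to 100, 21.9% at ranks 751 to 1115 and 28.3% among weaker candidates at ranks 1116 to 1500. The X-linked genes with named peaks included epn-1, nipi-3, eef-1A.2, nhr-1, nhr-32, atf-4 and akt-2.

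**Figure D4:**
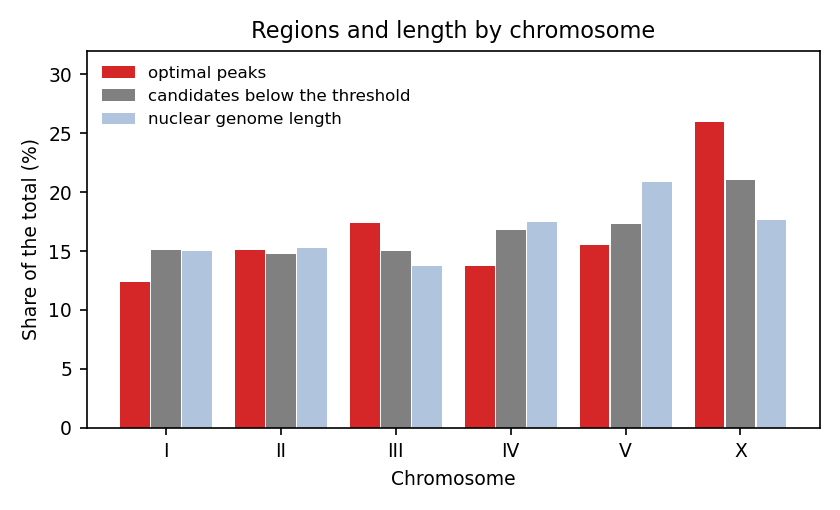
Share of the total (%) on each nuclear chromosome for the 1115 optimal peaks (red), the 28885 weaker candidates (grey) and genome length (blue). Chromosome X holds 25.9% of optimal peaks, 21.0% of weaker candidates and 17.7% of the length.

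Optimal peaks lay near small non-coding RNA genes more often than the weaker candidates did. Whether the signal there is specific to MDL-1 was not tested. Summits lay within 200 bp of a tRNA, snoRNA, snRNA, rRNA or miRNA gene in 75 optimal peaks (6.73%, interval 5.33% to 8.36%) and in 1.49% of the weaker candidates (ratio 4.51, Fisher's exact test, two-sided, p = 1.1e-24). By Fisher's exact test, the ratio was 12 at snRNA genes (13 peaks, adjusted p = 4.0e-09), 6.86 at snoRNA genes (27 peaks, adjusted p = 1.1e-12), 3.08 at tRNA genes (29 peaks, adjusted p = 7.3e-07) and 2.63 at miRNA genes (6 peaks, adjusted p = 0.042). No optimal peak was near an rRNA gene, and 0 of 1115 allows a share of up to 0.33%.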

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

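The alternatives restricted to peaks with or without CACGTG, and the single-replicate checks of the mdl-1 signal, were chosen after seeing the data. Of 466 values recomputed under alternatives, 358 kept their direction and their side of the threshold or moved little, 30 gained a call, 7 lost one, 60 changed direction and 11 moved. Most that changed direction belonged to lists or motifs not called at first, many with few bound members, and the cause was not tested. The longevity list was called under each of the 8 alternatives set before the data were examined (ratio 3.42 to 14.6, adjusted p 6.3e-08 to 0.023, exact tests). The promoter share, the E-box ratio, the chromosome X ratio and the share at non-coding RNA genes kept their direction and their side of the threshold under each alternative run. Leaving out a replicate moved the E-box ratio to between 8.04 and 12.5 and the number of called gene lists to between 2 and 4. Without replicate 1 the exact test also called glycolysis (4 of 19, adjusted p = 0.018) and insulin and TOR signalling (5 of 23, 0.0056). Of the optimal peaks, 829 were among the 1115 strongest regions of replicate 2 and 964 among those of replicate 1. With the stronger peaks alone, 557 peaks and 315 genes remained by construction and 1 list was called. Pearson's r (0.661) lay above Spearman's rho. The number of called lists rose to 4 with the window of 500 bp upstream to 100 bp downstream, to 10 with 2000 bp upstream to 500 bp downstream, to 10 with the single nearest 5' end and to 4 with peaks counted once among candidate regions, and the cause was not tested. Of lists not called at first, insulin and TOR signalling and autophagy were each called in 4 of 8 alternatives, nuclear hormone receptors and glycolysis in 3, cuticle collagens (lower) and lipid metabolism in 2, and the Myc-Mondo-Mad network, basic helix-loop-helix factors, heterochronic and molting genes, translation factors and the vacuolar ATPase list in 1. With only peaks without CACGTG, 3 lists were called, namely longevity (12.8), ribosomal proteins (5.13) and insulin and TOR signalling (6.65). With only CACGTG peaks, which leave few bound genes, 0 lists were called. The ratio was then 0 for longevity, the Myc-Mondo-Mad network, insulin and TOR signalling, translation factors, vacuolar ATPase, heterochronic and molting genes, body wall muscle, cathepsins, the cell cycle, chaperones, histones, neurons, nucleotide synthesis, pharynx, the proteasome, the respiratory chain and ribosome biogenesis. It was 2.00 for ribosomal proteins and rose for nuclear hormone receptors (2.39, 4 bound members) and, with 1 bound member each, for glycolysis (8.62), autophagy (6.06), basic helix-loop-helix factors (3.99), lipid metabolism (3.72) and germline (2.27). Ribosomal proteins also lost their call with the stronger peaks alone (3.87) and against genes with a candidate region (2.29). With the stronger peaks alone, the ratio fell to 0 for heterochronic and molting genes, body wall muscle, cathepsins, pharynx, the proteasome, the respiratory chain and ribosome biogenesis, and to 0.783 for histones. Against genes with a candidate region it fell to 0.839 for heterochronic and molting genes and for nucleotide synthesis, 0.899 for cathepsins, and 0.787 for the respiratory chain and for ribosome biogenesis. With peaks counted once it was 0.673 for heterochronic and molting genes, 0.997 for nucleotide synthesis, 1.68 for germline and 1.25 for homeobox factors. Cathepsins had 0 in the narrower window, 0.792 in the wider window and 0.796 with the nearest 5' end, which also gave 0.969 for the respiratory chain and 2.79 for EGR and Kruppel zinc fingers. When a replicate was left out, the ratios spanned 0 to 1.73 for heterochronic and molting genes, 0 to 2.13 for tRNA synthetases, 0.845 to 0.867 for the cell cycle, 0.793 to 2.03 for histones, 0 to 1.78 for pharynx, 0 to 0.999 for the proteasome, 0.716 to 1.40 for the respiratory chain and 0.944 to 1.24 for GTAAACA. Against GC-matched summits the hexamers higher at summits fell to 104, and GCGTGG (0.851), GGGCGG (0.930), TATAAA (1.39), CAGCTG (0.902), GTGGGC (0.735), TGATAA (1.49) and GTAAACA (1.70) changed direction. So did CAGCTG (0.929) and CATATG (1.22) with 25 bp either side and GTAAACA (1.17) with 100 bp, and the cause was not tested. No paired analysis was possible because the series holds 1 group. Read depth is unknown, so no limit from depth could be set.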

Other observations

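The test of chromosome X against the weaker candidates, the pairings of peak classes and the flanking bases of the E-box were chosen only after the results, or the share of candidates on X, had been seen.

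Peaks fell into kinds by sequence. CACGTG without GAGAGA or AGACGC was at 134 summits, GAGAGA or AGACGC without CACGTG at 441, both at 80 and neither at 460. Both occurred together less often than independent placement gives (99.99 peaks, Fisher's exact test, adjusted p = 0.0063 over 11 pairs). Peaks with CACGTG were among the 1115 strongest regions of both replicates more often than other peaks (76.6% against 61.4%, Fisher's exact test, adjusted p = 0.00026). Rank in the pooled list was not held fixed. Its median was 471.5 with CACGTG only, 276 with both, 542 with GAGAGA or AGACGC only and 634 with neither. The share of peaks with CACGTG in promoter windows was not shown to differ (49.5% against 49.7%, exact test, adjusted p = 1). Peaks with GAGAGA or AGACGC were less often on chromosome X (20.7% against 30.5%, exact test, adjusted p = 0.0012). Of the 75 peaks near non-coding RNA genes, 5 held a CACGTG (6.67% against 20.1% of other peaks, exact test, adjusted p = 0.0076), and GAGAGA or AGACGC was also less frequent there (28% against 48.1%, adjusted p = 0.0027). None of the optimal summits assigned to the 8 bound longevity and stress genes, among them zip-2, hlh-30, atf-4 and xbp-1, had a CACGTG within 50 bp. Only 19.2% of all optimal summits had one, so few would be expected at 8 genes, and the difference was not tested.

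Among the 225 E-boxes in summit windows, the symmetric form GCACGTGC made up 8.0% and 2.35% of the 17729 E-boxes in the nuclear genome (exact binomial test, adjusted p = 8.0e-05 over 10 forms). TCACGTGA made up 4% against 7.15% (exact binomial test, adjusted p = 0.099). ACACGTGC (ratio 1.92, adjusted p = 0.0043) and GCACGTGA (1.88, 0.0043) were also over-represented by the exact test. ACACGTGG (8.89% against 19%, adjusted p = 0.0002) and ACACGTGT (ratio 0.424, adjusted p = 0.039) were under-represented by the exact test. The summit windows held 1.27% of all E-boxes in the genome. This comparison was not matched for base content.

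One note in the labels names KLU-1 as the tagged protein. It was predicted that, had KLU-1 been precipitated, sites of its EGR-like class would outrank the E-box. The E-box ratio over flanks was 9.73, above both EGR-type sites (3.56 and 1.80). Against GC-matched weaker summits it was 4.12, and those of the EGR-type sites were 0.851 and 0.735. These values argue against a sample of KLU-1 only if KLU-1 binds such sites, which was not measured here. Whether E-boxes mark sites that gather signal in any ChIP was not tested. An insertion of klu-1 was predicted to raise signal around that gene, and its percentile was 59.1. No insertion known to raise signal served as a control, so this value cannot decide whether klu-1 was inserted. Whether the signal beside mdl-1 comes from extra copies in the transgene or from binding there was not tested.

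GAGAGA at summits was weighed against 2 technical explanations. Base composition would leave no more than a 1.5-fold excess over GC-matched weaker summits, and the ratio was 2.33. Noise of 1 library would place GAGAGA in regions found once. It was more frequent in shared regions, with a ratio of 1.19 in replicate 1 (Fisher's exact test, p = 0.044) and 1.35 in replicate 2 (p = 0.0016). Rank was not held fixed, and the share fell with pooled rank, from 32.9% at ranks 751 to 1115 to 19.5% at ranks 1501 to 2230. A technical cause present in both libraries cannot be seen in this comparison. What stays open is that such sequences may mark open chromatin that gathers signal in any ChIP. Peaks with GAGAGA or AGACGC were in promoter windows in 50.3% against 49.2% of others (Fisher's exact test, adjusted p = 0.879). That comparison cannot decide this, as both groups were optimal peaks and open chromatin was not measured. Other factors were not analysed here, and no biological explanation was tested.

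The excess on chromosome X was weighed against 3 explanations. The share on X was 1.23 times that of all weaker candidates, which argues against the candidate list as the whole cause, but candidates at ranks 1116 to 1500 held 28.3%, so this does not separate the optimal list from regions just below it. Clusters of neighbouring peaks would vanish on merging, but of 707 clusters 27.6% were on X, against 17.7% of the length. A single library did not carry it, the lower of the 2 replicates having 26.5% of its top regions on X. No biological explanation was tested, and the mappability of each chromosome was not determined.

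It was also asked whether regions found in 1 replicate were less specific. CACGTG was in 22% of shared and 10.8% of unshared top regions of replicate 1 (Fisher's exact test, p = 2.1e-06), and the lower ratio was 2.02, in replicate 2 (p = 9.8e-06). These comparisons did not hold rank fixed, and the share with CACGTG fell with pooled rank. It was 34% at ranks 1 to 100 and 13.97% at ranks 751 to 1115. The comparisons therefore cannot decide whether unshared regions hold fewer bound sites than shared regions of the same rank. The flanks of optimal peaks held CACGTG in 1.97%, a difference from unshared regions that was not tested.

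The threshold may also leave out bound sites. Of the next 1115 pooled regions, 100 (8.97%, interval 7.36% to 10.8%) held CACGTG, against 1.70% of their flanks (exact McNemar test, p = 1.8e-14). These flanks were not matched for base content. Weaker summits matched in base content to the optimal peaks held CACGTG in 4.66%, and the difference from that share was not tested. A reproducibility model fitted to the replicate lists passed 1591 pairs at 0.05 and 1020 at 0.01, above and below the 1115 optimal peaks. The passing pairs overlapped 93.2% and 85.2% of the optimal peaks.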
